A study of Capra hircus with 18 samples.

How the data were processed

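Mammary gland tissue of goats at 4 days of pregnancy (46, 70, 90 and 110) and at day 40 of lactation was compared on 18 arrays of 2 colours, arranged in 9 dye swaps. Per the labels' protocols, frozen tissue was ground in liquid nitrogen, total RNA was extracted with Trizol, purified on columns and treated with DNase, and 10 µg was reverse transcribed into amino-modified cDNA to which Cy3 or Cy5 was coupled. Which stage was in which dye was taken from the labels.

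The authors deposited the scanner software's output of each array, with the spot and local background intensity of both channels. Per the file headers, these were made with Agilent Feature Extraction 9.1.3.1, which also gave a processed signal per channel. The authors also deposited a table of log2 ratios of Cy5 over Cy3 for the same arrays. Set against the scanner values, these followed the log2 ratio of the median red over green foreground, with r from 0.78 to 0.98 across probes and slopes from 0.57 to 0.96. Their medians lay between 0.0018 and 0.024, and swapped arrays were not turned. How the authors removed the intensity trend is not given in the sources used here. The scanner intensities were the basis of the results, and the deposited ratios an alternative.

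Each array held 23232 spots in 48 blocks of 484. Of these, 21632 were probe spots, 960 were named empty, 260 were buffer and 380 carried 1 of 29 control names. The control type column marks no spot as a control, so controls were recognised by name. The mean foreground and median background of both channels were corrected with limma's normexp method and an offset of 50, fitted on all spots. Ratios were normalized within each array by loess (span 0.3, 4 iterations), with empty, buffer and control spots and spots flagged as outliers given no weight. Flagged spots were then set missing and saturated spots kept. From 4 to 30 probe spots per channel were saturated. Spots of 1 probe were averaged. Ratios were turned to the later over the earlier stage, and the mean of a swap was taken only where both arrays gave a value, which cancels the dye effect. An expected effect of the offset is that changes of dim probes are understated.

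A probe was to be tested if the scanner software flagged it as well above background in at least 50% of the channel measurements of a stage and if it had a value in at least 7 of the 9 swaps. The flag was set for at least 99.5% of the spots in every channel, so it removed none of the 21586 probes, and the number of swaps removed 3869. The remaining 17717 probes were fitted with lmFit and eBayes (limma 3.58.1, R 4.3.3) with 4 stage coefficients, which left 5 residual degrees of freedom. Of these probes 8900 lacked a swap, so the standard error of each comparison and the F statistic were worked out from the swaps each probe had, with limma's moderated variances. A first run had used limma's contrasts.fit, whose standard errors are approximate where values are missing, and this was corrected after its results had been seen. The correction multiplied single standard errors by 0.62 to 1.35 and changed the counts from 363 to 368 for the 5 stages, from 29 to 20 for P90 against P70 and from 354 to 368 for L40 against P110. P110 against P90 stayed at 0, and the comparisons with P46 were not affected. The 4 coefficients were tested together with the moderated F-test, and 6 comparisons were taken from the same fit. Adjusted p-values are those of Benjamini and Hochberg within a comparison, with a threshold of 0.05. Levels per stage were made from the loess ratios and quantile-normalized mean intensities of each channel, averaged within a swap, then over swaps.

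The steps were tested on simulated data with 200 changed probes, drawn with the real spread and missing values over 17717 probes. A log2 change of 2 was called for 87.5% of the probes changed in P70 against P46, 88.2% in P90 against P70, 94.1% in P110 against P90 and 93.8% in L40 against P110. A log2 change of 1 was called for 70.6%, 50%, 58.8% and 52.9% in the same order, and a change of 0.5 for 5.88%, 23.5%, 12.5% and 0%. With no changed probe, no call was made. Each of these shares rests on 16 or 17 probes. The simulated noise was normal and independent between probes, and few probes changed, so the rates need not carry over to the real arrays.

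Before the data were examined, 24 gene lists and a rule for naming genes had been fixed. The files name probes only by identifiers and the table of goat genes used here matched none of them, so the list tests were not run and no gene was named. In place of the 10 genes per direction that the rule takes, the 2 probes with the largest rise and the 2 with the largest fall were named in each comparison, a choice made after the files were seen, among those past the threshold whose direction both arrays of the direct swap showed, where there was a direct swap.

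The alternatives were other background corrections, spot signals, normalizations, filters, variance models and thresholds, the deposited ratios, arrays as replicates with the swap as a random block or with a dye term per scan date, and each swap left out in turn. The files give 3 scan dates, with 5, 10 and 3 arrays. With a dye coefficient, only the date with 10 arrays could be fitted alone.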

Results

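Gene expression was measured in goat mammary gland tissue at 5 stages, 4 in pregnancy and 1 in lactation. The stages were day 46 (P46), day 70 (P70), day 90 (P90) and day 110 (P110) of pregnancy and day 40 of lactation (L40). Total RNA of 2 stages was reverse transcribed, labelled with the fluorescent dyes Cy3 and Cy5 and hybridised together on a spotted oligonucleotide slide, so that each array gave the ratio of 2 stages for every probe. The 18 arrays formed 9 dye swaps, each a pair of arrays of the same 2 stages with the dyes exchanged. Every pair of stages met directly except P46 and L40, which the labels say were left apart as too different. Where a swap is left out, it is written as later/earlier stage. P46 and L40 each took part in 3 swaps, and P70, P90 and P110 each in 4. The series follows the differentiation of the gland during pregnancy, and the comparisons below take the steps of that time course in order, then P110 and L40 against P46.

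The labels name no animals, so the 2 arrays of a swap were counted as 1 replicate, and p-values measure only the spread between swaps, which may be technical. The number of arrays limits the precision. Each array held 21632 probe spots for 21586 probes. The files do not pair these probes with genes, so changes are given by probe identifier, for at most 2 probes that rose and 2 that fell in a comparison. The median net signal of the probe spots ranged from 52.6 to 158 in Cy5 and from 25.6 to 247 in Cy3. Between 45.4% and 96.2% of the probe spots of a channel, with a median of 81.6%, lay above the 95th percentile of the empty and buffer spots of that channel. The array of P90 against L40 on slide 16 stood at the low end, with 45.4% in its L40 channel and 21.5% of its spots flagged as outliers, against a median of 7.90% over the arrays. After filtering, 17717 probes were tested. Changes are fitted to the ratios of the swaps, while stage levels average single channels over swaps with different partners, so the 2 need not match. For 9 of the 19 named changes the levels gave a change that differed by over 1.5-fold, and these are given below. Over the alternative settings, 528 values of the named probes kept their direction, and 88 of these no longer passed the threshold. These probes were picked for large changes on the same arrays, which favours a kept direction.

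The 2 arrays of a swap correlated across probes with a Pearson r of 0.68 for P70 against P46, 0.59 for L40 against P110, 0.56 for P110 against P46, 0.51 for L40 against P90, 0.43 for P90 against P46, 0.40 for L40 against P70 and 0.33 for P90 against P70. The correlation was 0.09 for P110 against P70 and -0.0019 for P110 against P90. The direct ratio of a swap was also set against the estimate for the same stages from the other 8 swaps. Those correlations were 0.67 for L40 against P70, 0.67 for L40 against P110 and 0.61 for L40 against P90. They were 0.37 for P110 against P46, 0.36 for P70 against P46 and 0.16 for P90 against P46, and from 0.19 to 0.25 for the swaps among P70, P90 and P110. Probes are not independent replicates, and no test was made of these correlations.

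**Figure D1:**
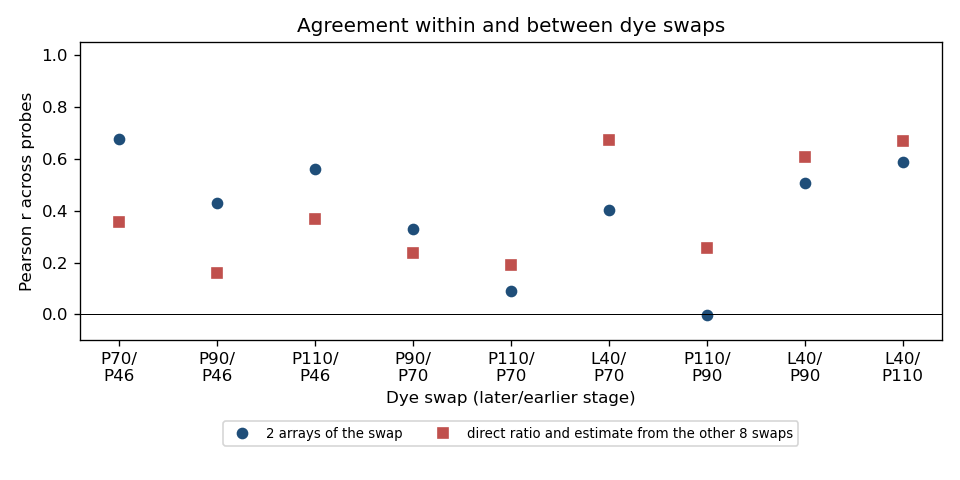
Pearson r across probes for each of the 9 dye swaps, named as later over earlier stage. Circles stand for the 2 arrays of the swap and squares for the direct ratio against the estimate from the other 8 swaps. The squares of the 3 swaps with L40 lie from 0.61 to 0.67, above those of the 6 swaps within pregnancy, which lie from 0.16 to 0.37.

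Across the 5 stages, 368 of the 17717 probes changed (limma's moderated F-test, adjusted p below 0.05). Of these, 124 probes (33.7%) had their highest estimate at L40, 98 (26.6%) at P46 and 80 (21.7%) at P70, while 40 were highest at P110 and 26 at P90. The lowest estimate fell at P46 for 130 probes, at L40 for 117 and at P110 for 67. The most frequent combinations were highest at L40 and lowest at P46 (59 probes), highest at P46 and lowest at L40 (54 probes) and highest at L40 and lowest at P110 (43 probes). In the group highest at L40, the median probe stood 0.74 log2 units above its own mean over stages at L40 and -0.35, -0.10, -0.19 and -0.27 from it at P46, P70, P90 and P110. The group highest at P70 had a median of 0.63 at P70, then -0.14 at P90 and 0.21 at P110. The count ranged from 26 at an adjusted p below 0.01 to 5798 with median centring in place of loess. With 1 swap left out it was 1181 without P90/P46, 111 without P90/P70, 148 without P110/P70, 63 without L40/P70, 99 without P110/P90, 34 without L40/P90 and 33 without L40/P110.

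**Figure D2:**
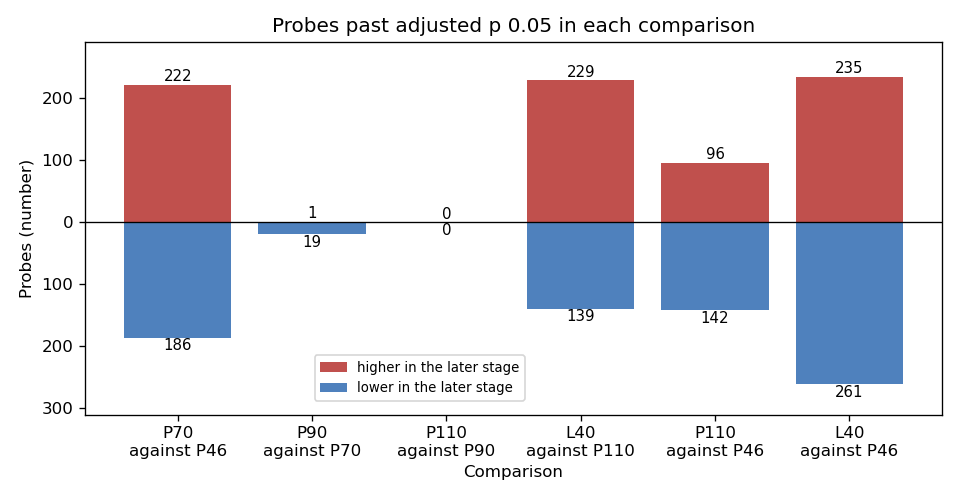
Number of probes past an adjusted p of 0.05 in each of the 6 comparisons, with probes higher in the later stage drawn above 0 and probes lower in it drawn below. P70 against P46 and L40 against P110 have 408 and 368 probes, and P110 against P90 has 0.

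Between day 46 and day 70 of pregnancy, OLIGO_08556 and OLIGO_12484 rose and OLIGO_10383 and Bt00003648 fell. OLIGO_08556 was 5.12-fold higher at P70 (log2 change 2.36, SE 0.26, adjusted p = 0.022), and the direct arrays gave 1.98 and 1.76. OLIGO_12484 was 5.07-fold higher (log2 change 2.34, SE 0.27, adjusted p = 0.013), with 2.78 and 2.81 on the direct arrays. Its normalized log2 intensity was 9.86 ± 0.55 (SD, n = 3 swaps) at P46 and 11.87 ± 0.89 (SD, n = 4) at P70. OLIGO_10383 was 5.62-fold lower (log2 change -2.49, SE 0.40, adjusted p = 0.033). Its levels were 11.90 ± 0.75 (SD, n = 3) at P46 and 10.30 ± 0.61 (SD, n = 4) at P70, a smaller difference of -1.60. Bt00003648 was 3.24-fold lower (log2 change -1.70, SE 0.30, adjusted p = 0.039). Without P70/P46 the change of OLIGO_10383 was -1.20 and missed the threshold, and without P110/P46 it was -3.35. Of 30 alternatives each, OLIGO_10383 missed the threshold under 14 and Bt00003648 under 11, among them those without P70/P46, P110/P70, L40/P70, L40/P90 or L40/P110. OLIGO_12484 missed it under 3 of 31, with plain background subtraction (2.51), with scaling between arrays (2.11) and without P70/P46 (1.95). OLIGO_08556 missed it under 3 of 22, with an offset of 0 (2.79), with processed signals (2.96) and with scaling (1.83). In total 408 probes changed, 222 higher and 186 lower at P70, and 111 of them by at least 2-fold. The median absolute change of the 408 was 0.76 log2 units. Leaving out 1 swap gave a count of 44 without P70/P46, 1557 without P90/P46, 210 without P110/P46, 176 without P90/P70, 62 without P110/P70, 76 without L40/P70, 165 without P110/P90, 57 without L40/P90 and 100 without L40/P110. The count fell to 4 with plain background subtraction, to 30 with an offset of 0 and to 1 when the arrays were also scaled to a common spread, and rose to 3254 with median centring, where 41.8% of the changed probes were higher against 54.4% with loess and 82.8% of the 29 found with processed signals.

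Between day 70 and day 90, 19 of the 222 probes that had risen by P70 fell, and these were all the probes that fell. OLIGO_12484 was 7.27-fold lower at P90 (log2 change -2.86, SE 0.25, adjusted p = 0.0034), and the direct arrays gave -2.73 and -2.39. OLIGO_08556 was 5.92-fold lower (log2 change -2.57, SE 0.25, adjusted p = 0.032), at 7.75 ± 0.28 (SD, n = 4) against 10.26 ± 0.71 (SD, n = 4) at P70. Bt00000212 was 2.21-fold higher at P90 (log2 change 1.14, SE 0.16, adjusted p = 0.049) and was the only probe that rose, but missed the threshold under 13 of 31 alternatives, among them those without P70/P46, P110/P70, L40/P70, P110/P90, L40/P90 or L40/P110 (adjusted p from 0.081 to 0.21 without these swaps, and from 0.00052 to 0.21 over all 31). The comparison had 20 changed probes, 1 higher and 19 lower at P90, of which 17 changed by at least 2-fold. OLIGO_12484 missed the threshold under 1 of 31 alternatives, with scaling between arrays (-3.38), and OLIGO_08556 under 3 of 22. Both steps use the P70 estimate, so a high value at P70 enters both, and a fall of probes that had risen is no separate evidence of a return. Leaving out 1 swap moved the count to 35 without P110/P46, 9 without P90/P70, 11 without P110/P70, 9 without P110/P90, 9 without L40/P90 and 11 without L40/P110. It was 68 with median centring, where 54.4% of the changed probes were higher against 5% with loess.

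Between day 90 and day 110, no probe passed the threshold of limma's test. At an unadjusted p below 0.05 there were 1054 of 17717 probes, and the smallest adjusted p was 0.077. The log2 changes had an SD of 0.18 across probes, against 0.29 for P70 against P46 and 0.31 for L40 against P110. With each array counted as a replicate 77 probes passed. This treats the 2 arrays of a swap as independent, which by itself can raise the count. With the swap as a random block 45 passed. With that block, 18 passed without slide 17, whose number in the labels lies outside the series of the other slides. Without slide 16, a choice made after the data were seen, 46 passed. Leaving out 1 swap gave 36 without P70/P46 and 6 without P90/P46.

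From day 110 of pregnancy to day 40 of lactation, OLIGO_11838 and OLIGO_09278 rose and OLIGO_12360 and OLIGO_05563 fell. OLIGO_11838 was 32.3-fold higher at L40 (log2 change 5.01, SE 0.31, adjusted p = 0.0023). Its levels were 7.63 ± 0.30 (SD, n = 4) at P110 and 13.40 ± 1.16 (SD, n = 3) at L40, a larger difference of 5.76. The direct arrays gave 4.14 and 4.37, and the swaps of L40 with P70 and with P90 gave 5.03 and 5.54. Without L40/P110 the change was 5.77, with median centring 3.68 and after scaling between arrays 11.95. OLIGO_09278 was 23.6-fold higher (log2 change 4.56, SE 0.51, adjusted p = 0.0099), with 4.51 and 4.14 on the direct arrays. The arrays of L40 with P90 gave 5.76 and 2.88. The swap of L40 with P70 lacked an array, and its remaining array gave 2.58. The probe had a level of 11.05 ± 0.21 (SD, n = 3) at L40 and a difference of levels of 3.96. Its change was 3.77 with median centring and 7.97 after scaling. OLIGO_12360, a bright probe at 14.71 ± 0.28 (SD, n = 4) at P110, was 5.99-fold lower at L40 (log2 change -2.58, SE 0.38, adjusted p = 0.022). The change was -4.17 with median centring and -4.53 after scaling, and with an offset of 0 it missed the threshold (-2.59). OLIGO_05563 was lower at L40 (log2 change -2.44, SE 0.24, adjusted p = 0.0099), but only 2 of its 6 L40 measurements lay above the empty spots, so the size of the fall is not known. Its direct arrays gave -1.16 and -3.76, and the estimate was -4.94 with processed signals and -2.24, past the threshold no longer, with the spots flagged as outliers kept. Without L40/P90 or L40/P110, OLIGO_09278 (4.33 and 4.92) and OLIGO_12360 (-2.75 and -2.33) missed the threshold. In total 368 probes changed, 229 higher and 139 lower at L40, and 137 by at least 2-fold, of which 98 were higher. The count with 1 swap left out was 557 without P70/P46, 206 without P90/P70, 176 without P110/P70, 91 without L40/P70, 120 without P110/P90, 54 without L40/P90 and 5 without L40/P110. Slide 17, with a label number outside the series of the others, is 1 of the 2 arrays of L40/P110. With arrays as replicates and the swap as a random block the count was 687, and 596 without slide 17. The count of the main test was 71 with an offset of 0 and 6843 with median centring, where 46.5% of the changed probes were higher against 62.2% with loess. This share was 49.9% after scaling between arrays, 48.8% with processed signals and 44.6% of 551 probes with plain background subtraction.

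Over the whole of the pregnancy sampled, from day 46 to day 110, Bt00007213 was 7.90-fold higher at P110 (log2 change 2.98, SE 0.24, adjusted p = 0.0052). Its levels were 7.28 ± 0.57 (SD, n = 3) at P46, 8.61 ± 1.16 (SD, n = 4) at P70, 8.74 ± 0.41 (SD, n = 4) at P90, 9.82 ± 0.05 (SD, n = 4) at P110 and 7.99 ± 0.14 (SD, n = 3) at L40. OLIGO_05563 was 6.73-fold higher (log2 change 2.75, SE 0.27, adjusted p = 0.022), with 2.78 and 3.13 on the direct arrays. OLIGO_01108 was 6.28-fold lower (log2 change -2.65, SE 0.39, adjusted p = 0.041) and OLIGO_10383 5.84-fold lower (log2 change -2.55, SE 0.40, adjusted p = 0.036), the latter missing the threshold under 13 of 30 alternatives. The direct arrays gave less, -1.94 and -1.83 for OLIGO_01108 and -1.64 and -1.73 for OLIGO_10383, as did the levels, with differences of -1.72 and -1.86. The fit of OLIGO_01108 also used the swap of P70 with P46, in which its P70 level was 7.84 against 10.10 to 10.14 in the other swaps. Without P70/P46 the change of OLIGO_10383 was -1.69 and without P110/P46 -3.84. It missed the threshold without P90/P70, P110/P70, L40/P70, P110/P90, L40/P90 or L40/P110. OLIGO_01108 missed it under 5 of 23, with plain background subtraction (-3.00), an offset of 0 (-2.91), processed signals (-2.99) or scaling between arrays (-1.61) and without L40/P110. Bt00007213 missed it under 2 of 31, with plain subtraction (4.12) and with scaling (2.08), and OLIGO_05563 under 2 of 22, with scaling (1.74) and with the deposited ratios (3.58). The comparison had 238 changed probes, 96 higher and 142 lower at P110. Of these, 158 had also changed at P70 against P46, but both comparisons use the P46 estimate, which alone can give shared probes and directions, and no reference value for this overlap was computed. The count was 0 with plain background subtraction, 0 with scaling, 11 with processed signals and 13 with an offset of 0. The count became, with 1 swap left out, 1176 without P90/P46, 121 without P90/P70, 93 without P110/P70, 17 without L40/P70, 21 without P110/P90, 17 without L40/P90 and 22 without L40/P110. The swap P110/P46, without which the count was 17, is the 1 direct measure of these stages, and in it the 50 probes most raised at L40 in the swaps without P46 stood a median of 0.99 higher at P46 than at P110. It is thus not known how far the probes called lower at P110 rest on the P46 material of that swap. The count was 559 with median centring, where 15% of the changed probes were higher against 40.3% with loess.

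**Figure D3:**
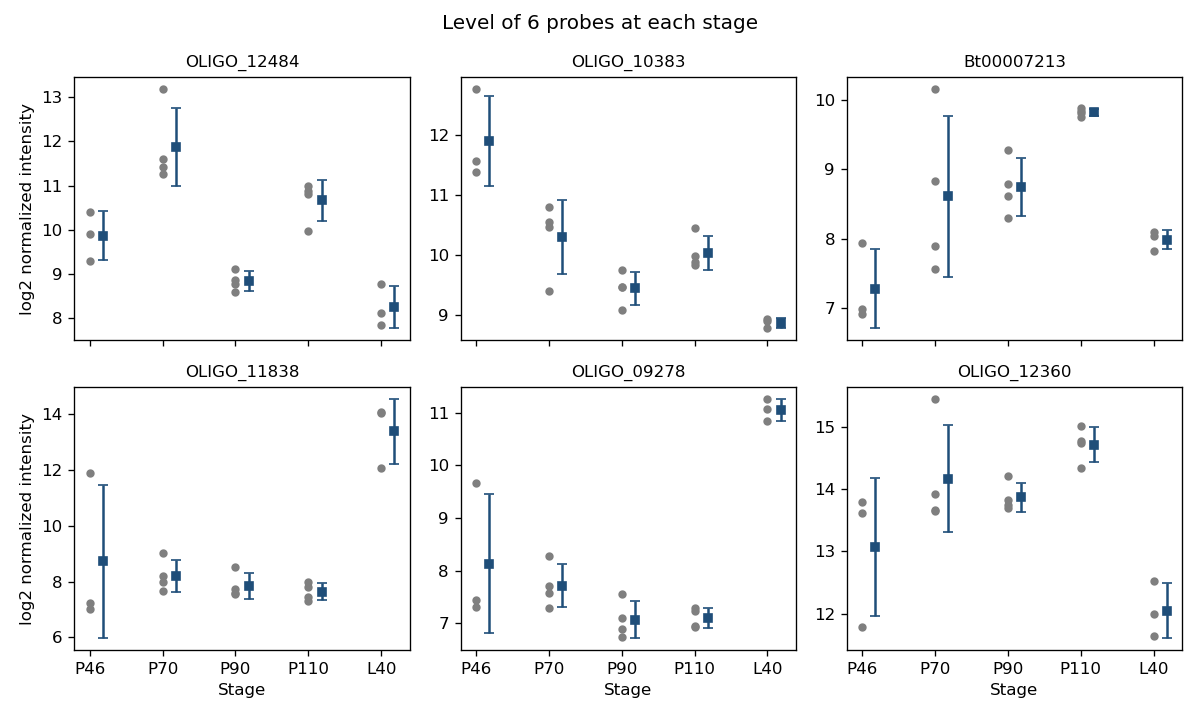
Normalized log2 intensity of 6 probes at each stage. Grey circles are the swaps, each the mean of its channel values at that stage, and squares with bars are the mean and SD over swaps. OLIGO_11838 and OLIGO_09278 stand highest at L40, with means of 13.40 and 11.05, and in both probes 1 of the 3 swaps lies far above the other 2 at P46.

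L40 and P46 were never hybridised together, and their difference was estimated through the other stages. OLIGO_11838 was 44.2-fold higher at L40 than at P46 (log2 change 5.46, SE 0.41, adjusted p = 0.0080). Its P46 level was 8.72 ± 2.75 (SD, n = 3), because the swap with P110 gave a P46 value far above the other swaps, and the difference of levels was 4.67. That swap did not enter the estimate, since 1 of its arrays was flagged for this probe. With flagged spots kept the change was 3.89, and with the deposited ratios 3.76, and neither passed the threshold, nor did the 14.67 after scaling between arrays. Bt00000159 was 27.1-fold higher (log2 change 4.76, SE 0.50, adjusted p = 0.016). This rested on the swap of L40 with P70, at 4.59, since the swaps of L40 with P90 and P110 each lacked an array, and their remaining arrays gave 1.16 and 0.09. The change was 2.08 with flagged spots kept, 2.23 with the deposited ratios and 1.89 on the 10 arrays of 1 scan date, and none of these passed the threshold, while after scaling it was 18.86 and the levels differed by 2.27. OLIGO_10383 was 13.7-fold lower at L40 (log2 change -3.78, SE 0.48, adjusted p = 0.017), at 8.87 ± 0.08 (SD, n = 3), with a difference of levels of -3.03. Bt00000310 was 11.4-fold lower (log2 change -3.51, SE 0.46, adjusted p = 0.017), but its levels of 12.81 ± 1.06 (SD, n = 3) at P46 and 11.49 ± 0.78 (SD, n = 3) at L40 differed by -1.32 only. Both missed the threshold without L40/P70, L40/P90 or L40/P110, and OLIGO_10383 was at -2.70 without P70/P46 and -4.86 without P110/P46. With median centring Bt00000310 was at -5.39. In total 496 probes changed, 235 higher and 261 lower at L40, and 218 by at least 2-fold. Leaving 1 swap out changed the count to 320 without P70/P46, 1068 without P90/P46, 289 without P90/P70, 300 without P110/P70, 25 without L40/P70, 305 without P110/P90, 38 without L40/P90 and 94 without L40/P110. It was 55 with an offset of 0 and 9587 with median centring, and in the P46 material of the swap with P110 the 50 probes most raised at L40 in the other swaps stood a median of 0.99 above P110.

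The share of a channel's net signal held by its 50 brightest probes was also compared. It averaged 25.9% ± 2.48 (SD, n = 3 swaps) at L40, against 17.6% ± 1.66 (SD, n = 3) at P46, 19.4% ± 1.31 (SD, n = 4) at P70, 17.4% ± 1.64 (SD, n = 4) at P90 and 18.9% ± 3.37 (SD, n = 4) at P110. In 5 of the 6 arrays with L40 the share was larger in the L40 channel than in the other channel, by up to 13.6 percentage points, and in the sixth the channels differed by -0.049. With 3 swaps, an exact two-sided sign-flip permutation test cannot give a p below 0.25.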

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

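The tests of the 3 patterns weighed here were chosen after the result was seen. The random assignments of ratios to stages were planned before.

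Probes raised in lactation were also high in the P46 material of 1 swap: the 50 probes most raised at L40 against P110 in the 6 swaps without P46 (median log2 change 2.10) were higher at P46 by a median of 0.99, in 44 of 50 probes, in the swap with P110, against -0.09 and -0.51 in the swaps with P70 and P90. None of 10000 random sets matched on level came as far above those swaps (1.49, against at most 0.21). The 50 probes were chosen for changing together at L40 and the random sets were not, so this gives no significance for 1 swap. For L40 material in place of P46 material, the median ratio to the L40 change was 0.45 (90th percentile 0.73), not near 1. The 50 probes were picked for the largest L40 changes, which by itself lowers this ratio, so the ratio alone cannot decide on such material. Over all probes, which were not picked, P46 minus P110 in this swap had an r of 0.19 with that L40 change. The direct ratios of the swaps with L40 had an r of 0.61 to 0.67 with the estimates from the other swaps. This argues against L40 material wholly in place of P46 material, though 1 swap was weighed and no test was made. Low P110 material alone is argued against, since the P46 channels of this swap lay 1.13 above those of the other swaps. A fixed share of L40 RNA stays open, since the implied share was 25% in the 25 most raised probes and 21.9% in the other 25, a quotient of 0.88, while the 50 probes most lowered at L40 (median -1.07) stood at -0.38 at P46 in this swap, against -0.53 and 0.16 in the swaps with P70 and P90, and did not set it apart. It may equally have been a gland still partly lactating at P46; the labels say nothing of the animals, and no biological explanation was tested.

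Ratios of different swaps disagreed for some probes by more than the 2 arrays of a swap: the variance was larger between than within swaps for 137 of 17717 probes (F-test, adjusted p below 0.05) and smaller for 0. In the 137 the median SD was 0.53 between and 0.091 within swaps. The 2 arrays of a swap also lay on different slides with the dyes exchanged, so noise of slide and dye is in the variance within swaps. For these probes the test thus shows a difference that both arrays of a swap shared. It cannot say whether a stage had the same extract in every swap, since the labels name no animals. The median log2 level of the 137 was 0.94 above that of all probes. They were picked by a ratio to the noise within swaps, so this level cannot decide on noise of dim probes. Over all 17717 probes the median ratio of the variance between swaps to that within swaps was 1.46. Among the brightest probes, which were not picked by this ratio, it was 2.23. The excess was thus not confined to dim probes, which argues against their noise as its only source over all probes. The difference between these 2 medians was not tested. In 112 of the 137 probes the largest residual fell in a swap with P46 (45 with P70, 51 with P90 and 16 with P110). Animals, pools and extracts all stay open as untested, and hybridisation only as far as both arrays of a swap shared it.

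The 50 brightest probes held a larger share of the signal at L40 than in the other channel in 5 of the 6 arrays, the exception being slide 12 (-0.049 percentage points, and -1.19 without background subtraction). A dye effect that is equal on both arrays of a swap cancels in the swap means. These were 4.95, 12.4 and 7.45 percentage points, with a mean of 8.26 ± 3.78 (SD, n = 3). The 2 arrays of each of these swaps were scanned on different dates, so a dye effect that differs by date need not cancel. Without background subtraction the mean was 5.11 ± 2.14 (SD, n = 3), so the difference did not vanish. With 3 swaps, neither a dye effect nor background subtraction is excluded as a contributor. Of the 9 equally weak pregnancy channels, 33.3% reached the lowest L40 share; they came from 2 of 7 swaps and are not independent, so weak signal and stage cannot be told apart with so few swaps. A lactating gland in which few transcripts make up more of the RNA is a candidate explanation, which stays open.

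Chance was tested with 100 assignments of the 9 swap ratios to the 9 stage pairs, the real one included. For the 5 stages the real count was 368 and the highest other 4, for P70 against P46 408 and 13, and for P90 against P70 20 and 3. For L40 against P110 they were 368 and 1, for P110 against P46 238 and 6, and for L40 against P46 496 and 2. In these 6 results only 1 assignment, the real one, gave as many, and the median of the others was 0. Reassigning all 9 ratios at once moves the real differences into the residual of every other fit. The ratios thus went together best under their own stages. Chance is not excluded for a single comparison, nor are chance differences between animals or extracts. For P110 against P90 the real count was 0, which all 100 reach by construction, so chance was not tested there (highest other 3).

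Of 42 groups of values, 4 held a value far from the others, where chance gives about 1 in 20. The rule needs at least 4 values, so the levels at P46 and L40, with 3 swaps each, were not tested. In the swap of P70 with P46, the P70 log2 level of Bt00003648 was 9.65 against 8.76 to 8.78 in the other swaps, that of OLIGO_12360 15.44 against 13.65 to 13.92, that of OLIGO_05563 11.33 against 7.82 to 8.09, and that of OLIGO_01108 7.84 against 10.10 to 10.14. Among control spots, which no comparison used, 8 of the 9 names outside the Alien and Rn series had a net signal above the empty spots in all 36 channel measurements, against 2 of the 20 names of those series. The spots of 1 of these 8 were saturated in 97.2% of measurements. The other 7 were lower at L40 than at P46 with median centring (log2 change from -2.21 to -0.97, median -1.62), while after loess, in which they had no weight, 3 of the 7 were lower (from -0.87 to 1.20, median 0.08), and this was not tested.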

How the results depend on the processing

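The alternatives marked below as later were chosen after the data were seen. Over 33 alternatives, each of the 528 values of a named probe kept its direction, 440 stayed past the threshold and 88 did not. Settings that change only the threshold gave no such values, and a probe not fitted under a setting was left out there. The probes were picked for large changes on the same arrays, which favours a kept direction. The counts depended far more on the processing: 88 of 231 stayed within 1.5 times. Both tallies include the setting without a signal filter, which repeats the reported fit by construction. They also include fits with arrays as replicates, whose smaller p-values can by themselves keep a probe past the threshold. Counts are given in the order 5 stages, P70 against P46, P90 against P70, P110 against P90, L40 against P110, P110 against P46 and L40 against P46, where the reported ones were 368, 408, 20, 0, 368, 238 and 496. They were 772, 155, 23, 1, 875, 111 and 937 without background subtraction, 110, 4, 10, 0, 551, 0 and 462 with plain subtraction (13312 probes tested), 31, 30, 10, 0, 71, 13 and 55 with an offset of 0, 309, 29, 16, 1, 684, 11 and 693 with processed signals, 5798, 3254, 68, 2, 6843, 559 and 9587 with median centring, 549, 1, 12, 0, 966, 0 and 705 with scaling between arrays after loess, and 953, 792, 43, 0, 862, 374 and 1066 with flagged spots kept (21586 probes tested). An adjusted p below 0.01 gave 26, 16, 10, 0, 45, 4 and 6, and a change of at least 2-fold in addition to the threshold gave 219, 111, 17, 0, 137, 80 and 218. With 18 arrays as replicates they were 3551, 2691, 178, 77, 1257, 2079 and 2439, with the swap as a random block (correlation 0.21) 2095, 1842, 81, 45, 687, 1331 and 1566, the same without slide 17 1591, 1441, 55, 18, 596, 1027 and 1237, with a dye term per scan date 2336, 620, 133, 0, 777, 1776 and 1797, and with the deposited ratios 1564, 401, 45, 0, 1696, 154 and 1685. Later alternatives gave 253, 289, 16, 0, 194, 141 and 356 with a value required in all 9 swaps (8817 probes tested), 2420, 1712, 91, 46, 1163, 1210 and 1948 without the dim slide 16 and with the swap as a random block, and 2110, 143, 67, 1, 1834, 1077 and 1947 on the 10 arrays of 1 scan date. Where fewer probes or arrays entered, or the threshold was stricter, the construction changes the count. Counting the 2 arrays of a swap as independent replicates also raises it by construction, since they may hold the same extracts. Otherwise the cause was not tested.

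Leaving out 1 swap moved most counts. They were 432, 44, 29, 36, 557, 198 and 320 without P46 with P70, 1181, 1557, 30, 6, 483, 1176 and 1068 without P46 with P90, 314, 210, 35, 0, 324, 17 and 346 without P46 with P110, 111, 176, 9, 0, 206, 121 and 289 without P70 with P90, 148, 62, 11, 0, 176, 93 and 300 without P70 with P110, 63, 76, 14, 0, 91, 17 and 25 without P70 with L40, 99, 165, 9, 0, 120, 21 and 305 without P90 with P110, 34, 57, 9, 0, 54, 17 and 38 without P90 with L40 and 33, 100, 11, 0, 5, 22 and 94 without P110 with L40. Each has 1 residual degree of freedom fewer and needs a value in 7 of 8 swaps.

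The share of higher probes was 54.4% for P70 against P46, 5% for P90 against P70, 62.2% for L40 against P110 and 40.3% for P110 against P46. With median centring it was 41.8%, 54.4%, 46.5% and 15%. With scaling between arrays it was 49.9% for L40 against P110, and the single probe of P70 against P46 was higher. With processed signals it was 82.8% for P70 against P46 and 48.8% for L40 against P110. Plain subtraction gave 44.6% for L40 against P110. All counts stayed within 1.5 times with the median foreground, loess within blocks, no signal filter, a flag in every channel, an intensity trend in eBayes and, as later choices, a local background or empty-spot filter. The filter on the flag removed no probe and says nothing about stability. Signal over background limits dim probes: in the weakest channel 45.4% of the spots lay above the empty spots. The alternatives for gene lists were not run, since no probe could be named.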

Other observations

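The comparisons here, and the tests by identifier, were chosen after the data were seen. The 4 stage pairs outside the planned comparisons gave 276 changed probes for L40 against P70 (133 higher and 143 lower), 136 for L40 against P90 (93 higher and 43 lower), 62 for P90 against P46 (32 higher and 30 lower) and 0 for P110 against P70. L40 thus had between 136 and 496 changed probes against each pregnancy stage, and P46 between 62 and 408 against the later pregnancy stages. Among P70, P90 and P110 the counts were 20, 0 and 0. Differences between these counts were not tested.

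Of the 408 probes changed at P70 against P46 and the 368 changed at L40 against P110, 46 were in both sets. In 18 of the 46 the direction was the same, and in the others it was opposite. Both comparisons come from the same fit, in which the swap P110/P46 enters both estimates. No reference value for this overlap was computed. Of the 496 changed at L40 against P46, 162 had changed at P70 against P46, but both comparisons use the P46 estimate, and no reference value for this overlap was computed.

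With median centring in place of loess, the brightest 10% of probes stood at a median of -0.94 and the dimmest 10% at 0.47 in L40 against P110, and at -1.16 and 0.70 in L40 against P46. The medians were -0.34 and 0.45 for P70 against P46, 0.27 and -0.22 for P90 against P70, -0.22 and 0.23 for P110 against P46 and -0.16 and -0.00064 for P110 against P90. Loess sets this trend to 0 on each array, so the changes reported are relative to probes of like brightness.

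The array carries probes of 2 identifier series, 13257 named OLIGO and 8329 named Bt. The share changed across the 5 stages was 2.19% of 11397 tested OLIGO probes and 1.87% of 6320 tested Bt probes (Fisher's exact test, two-sided p = 0.15, adjusted p = 0.56 over 7 results). P110 against P90 had no changed probe and could not differ, and none of the other 6 results differed between the series at an adjusted p of 0.05. For the 8 probes with 6 to 10 spots, the median SD of the log2 ratio between spots on an array was 0.14.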
